A study of Homo sapiens with 36 samples.

How the data were processed

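RNA from 4 triple-negative breast cancer cell lines, HCC1143, SUM159PT, HCC38 and HCC70, was measured on 36 whole-transcript expression arrays. Each line was treated with ruxolitinib, an inhibitor of the JAK1 and JAK2 kinases, at 1 µM for 4 h or 24 h, or with the vehicle DMSO at 0.1% for 24 h, which gave 12 groups of 3 arrays. Groups were taken from the labels, and the series describes the replicates of a group as separate experiments. Whether a replicate number joins arrays of the same experiment is not stated. Per the labels' protocols, biotinylated cRNA was prepared from 6 µg of total RNA per array. The values used were the deposited log2 intensities, which the authors made with RMA per the submitters' processing notes. The RMA version, the annotation and the set of arrays normalised together are not given there. The raw array images were not used here.

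The deposited table held 53617 probe sets. Of these, 16098 named 1 gene and 37519 named none in the probe table used, and no probe set named several. The named probe sets stood for 14884 genes, of which 779 had more than 1 probe set, and for those the probe set with the highest mean over all arrays was taken. A gene was tested when its highest group mean exceeded 5.92, the median of all deposited log2 values, which left 11814 genes. The level had to be passed in 1 group only, so for a single gene a log2 fold change with 1 group below it is read as a limit, and none is given where both groups lay below it. For an average over the lines the means over the lines were held to the level, so an average can take in lines in which the gene lay below it. Of 16 genes to be named whatever their values, 13 had a probe set carrying their name and were tested, and the others were not analysed here. Probe sets without a gene name were left out of all comparisons of genes and were tested apart, 18879 of them above the same level.

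One linear model with a mean for each of the 12 groups was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes without a trend), with 24 residual and 4.88 prior degrees of freedom. The contrasts were ruxolitinib against DMSO at 4 h and at 24 h within each line, their equal-weight averages over the 4 lines, and 24 h against 4 h of drug averaged over the lines. Moderated F tests asked whether the response at 4 h or at 24 h, or the DMSO level, differed between the lines. All tests were two-sided unless stated otherwise, p-values were adjusted by the Benjamini-Hochberg method over the 11814 genes of a contrast, and a gene was called at an adjusted p under 0.05. The only vehicle arrays were at 24 h, so the 4 h contrast also differs in time in vehicle, and the 4 h and 24 h contrasts of a line share their DMSO arrays. Values after ± are standard errors (SE) of a log2 fold change unless they are marked as standard deviations (SD).

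Groups of genes were tested with camera, the competitive set test of limma, with a preset inter-gene correlation of 0.01 and adjustment over the 17 lists within a contrast. The 17 lists were JAK-STAT targets, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory mediators, immediate early genes, G1/S cell cycle, G2/M cell cycle, apoptosis regulators, cholesterol synthesis, hypoxia and glycolysis, amino acid and stress response, basal epithelial, luminal epithelial, mesenchymal, leukocyte markers, endothelial and fibroblast markers, and JAK-STAT components. Lists, contrasts, tests, filters and alternatives set beforehand were fixed before the data were examined. Numbers of list members given below count the tested ones. The other members had no named probe set or failed the filter, so each list result covers only part of its list. Camera with the correlation estimated from the residuals, and fry, which asks whether the members of a list move one way on balance, were the alternatives for lists. Differences of the JAK-STAT target and interferon lists between pairs of lines were tested with camera on the difference of the contrasts, adjusted over the 12 tests of a time point. Overlaps of called genes between lines used one-sided Fisher exact tests.

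Genes named in the text were taken by a fixed rule, and not every gene it gave is printed. It took up to 10 called rises and 10 called falls with the largest log2 fold change in each averaged contrast against DMSO, and 5 and 5 in each other contrast. To these it added up to 4 called members of each list in an averaged contrast, the 10 genes with the smallest p in each F test of differing response, the 4 members of each of 4 lists (basal, luminal, mesenchymal, JAK-STAT components) with the smallest p between DMSO groups, and the 16 genes set in advance. A gene named outside this rule is marked as chosen after its values were seen.

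The alternatives set beforehand were a variance trend with robust moderation, no filter and a filter 1 log2 unit higher, the mean of all probe sets of a gene, centring each array on its median, fitting a line's own arrays alone, the replicate number within a line as a block, a covariate for arrays listed apart, and leaving out each array in turn. The 5 arrays listed apart from the rest of their line in the series were HCC1143 DMSO replicate 3, SUM159PT DMSO replicate 3, HCC70 DMSO replicate 3 and HCC70 4 h replicates 2 and 3. A covariate for the mean level of 1072 microRNA precursor genes, a block for the arrays listed apart within each line, and a fit without those 5 arrays were added after seeing the data, as was a covariate for the mean level of 5 YAP/TEAD target genes in fits of list means. Whether replicate numbers pair arrays was decided from correlations of the deviations from group means. In HCC38 all 9 correlations of same-numbered arrays exceeded 0.1 (0.196 to 0.726), so its numbers were read as pairs. The labels do not state this. Arrays numbered 1 and 2 also correlated across numbers there (0.219 to 0.419). The correlations thus set only replicate 3 apart, and the pairing of replicates 1 and 2 is an assumption.

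The procedure was tested on simulated data with the arrays' own means and spread, in which 50 genes were changed by each of 4 sizes. In the SUM159PT 24 h contrast, 27 of 50 genes (54%) changed by 0.5 log2 units were recovered, 47 (94%) of those changed by 1 and all 50 of those changed by 2 or 3, with 10 false calls among 184. In the averaged 24 h contrast 49 of 50 (98%) were recovered at 0.5 and all 50 at each larger size, with 13 false calls among 212. Simulated data without any change gave 0 calls in the averaged 24 h contrast and 0 in the F test. The simulated noise was drawn independently for each gene and array. It held no correlation between genes and no array sets, so these counts do not show the rate of false calls under such structure.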

Results

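The data were 36 arrays of 4 triple-negative breast cancer lines, with 3 arrays for each line under DMSO for 24 h, ruxolitinib for 4 h and ruxolitinib for 24 h. The design asked how an inhibitor of JAK1 and JAK2 changes gene expression in each line and whether the lines respond alike. Array medians over all probe sets lay between 5.89 and 5.98 log2 units. Arrays of the same group correlated at r = 0.979 to 0.993 over all 53617 probe sets and arrays of different lines at 0.922 to 0.961. These are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.134 within a line and 0.0671 for an average over the lines.

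Under DMSO the lines differed in epithelial and mesenchymal genes. GRHL2, a transcription factor of epithelial cells, stood at 10.49 ± 0.02 (SD, n = 3) in HCC1143 and 10.96 ± 0.28 in HCC70 against 5.83 ± 0.18 in SUM159PT and 5.82 ± 0.31 in HCC38. CLDN7, a tight junction protein, and ESRP1, an epithelial splicing regulator, were likewise high in HCC1143 (12.23 and 11.38) and HCC70 (12.10 and 11.82) and low in SUM159PT (7.50 and 5.96) and HCC38 (7.26 and 5.74). ZEB1, a repressor of epithelial genes, stood at 8.46 in SUM159PT and 8.42 in HCC38 against 6.09 in HCC1143 and 5.26 in HCC70, whereas AXL, a receptor tyrosine kinase, was low only in HCC70 (6.63) among the 4 lines and lay between 10.94 and 11.91 in the others. The desmosomal cadherin DSC3 was at 5.31 in SUM159PT and between 10.01 and 11.06 in the other lines. Of the signalling components, JAK2 was lowest in HCC1143 (6.41 ± 0.11) and highest in HCC38 (9.43 ± 0.41), and LIFR, the receptor of leukemia inhibitory factor, was highest in SUM159PT (11.61 ± 0.23) and lowest in HCC1143 (8.06 ± 0.28). The interferon-stimulated list had mean log2 levels of 9.65 ± 0.38 (SD) in HCC1143 and 9.33 ± 0.27 in HCC70, and of 8.16 ± 0.16 in SUM159PT and 7.58 ± 0.29 in HCC38. In all, 9349 of 11814 genes differed between the DMSO groups by limma's moderated F test, with adjusted p from 2.65e-24 for GRHL2 to 2.10e-11 for KRT15 among the genes named here.

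Averaged over the lines, 24 h of ruxolitinib lowered interferon-stimulated genes and JAK-STAT targets. The largest called falls were those of IFI44L, an interferon-induced gene (−1.61 ± 0.28 log2 units, 12 arrays against 12), and XAF1, a pro-apoptotic interferon-induced gene (−1.10 ± 0.18). NNMT, the nicotinamide N-methyltransferase, fell by 0.94 ± 0.10, the helicase gene DDX60 by 0.90 ± 0.18, the nuclear body gene SP110 by 0.87 ± 0.10 and IRF9, the DNA-binding subunit of the interferon-activated factor ISGF3, by 0.83 ± 0.10. OSMR, the receptor subunit for oncostatin M, fell by 0.65 ± 0.06 (adjusted p = 6.41e-07), and SOCS3, a feedback inhibitor of cytokine signalling, fell by 0.72 ± 0.09 (adjusted p = 2.08e-05). The chemokine gene CCL2 (−0.81 ± 0.20), the adhesion molecule gene ICAM1 (−0.80 ± 0.14), the metalloreductase gene STEAP4 (−0.81 ± 0.17) and the kallikrein gene KLK6 (−0.78 ± 0.17) were also among the 10 largest falls. Rises were smaller: ANXA9, an annexin, rose by 0.56 ± 0.09, the Eph receptor gene EPHB6 by 0.49 ± 0.09, and the ammonium transporter gene RHAG by 0.47 ± 0.10. CCDC160, a coiled-coil gene, was called higher with both means (5.05 and 5.51) below the filter level. The other 6 rises named were CIDEC (0.46 ± 0.11), REPS2 (0.41 ± 0.09), PLLP (0.41 ± 0.10), CRIP2 (0.37 ± 0.09), TFCP2L1 (0.34 ± 0.08) and EEPD1 (0.34 ± 0.08). The DMSO means of RHAG (5.84) and CIDEC (5.88) lay below the filter level. By the moderated F test the 24 h responses of RHAG, EPHB6, CIDEC, REPS2, CRIP2 and TFCP2L1 differed between the lines (adjusted p from 0.00112 for RHAG to 0.0300 for CIDEC). Each of these genes rose most in SUM159PT, so their averages are not read as a response shared by the lines. Of the falls, IFI44L, XAF1, DDX60, SP110, IRF9, CCL2 and STEAP4 also differed between the lines by this test. Their adjusted p ran from 0.00177 for SP110 to 0.0497 for DDX60. In SUM159PT, IFI44L stood at 7.95 under DMSO and 8.17 at 24 h. The averages of these falls are likewise not read as shared by the lines. In all 105 genes were called, 31 higher and 74 lower, and 25 of them changed by more than 1.5-fold. With the arrays listed apart as a block within lines 149 genes were called, and 89 of the 105 kept their call. JAK1, JAK2, SOCS2, PIM1, IRF1 and MYC were not called in any contrast. Of the called genes named here all but CCL2, CIDEC, PLLP, CRIP2, TFCP2L1 and EEPD1 kept their call without any 1 of the 24 arrays. CCL2 kept it only when the array left out was HCC1143 DMSO or 24 h replicate 3, SUM159PT DMSO replicate 1 or 2 or 24 h replicate 3, HCC38 DMSO replicate 1 or 24 h replicate 3, or HCC70 DMSO replicate 3 (adjusted p up to 0.0945). For CIDEC these arrays were HCC1143 DMSO replicate 2 or 24 h replicate 1, SUM159PT DMSO replicate 3 or 24 h replicate 1 or 2, HCC38 DMSO replicate 1 or 24 h replicate 3, and HCC70 DMSO or 24 h replicate 2 (up to 0.0974). For CRIP2 they were SUM159PT DMSO replicate 2 or 24 h replicate 3, HCC38 DMSO replicate 1 or 24 h replicate 3, and HCC70 DMSO replicate 3 (up to 0.0948). For PLLP they were HCC1143 DMSO replicate 1, SUM159PT DMSO replicate 3 or 24 h replicate 2, HCC38 DMSO replicate 1 or 24 h replicate 3, and HCC70 DMSO replicate 1 (up to 0.104). For TFCP2L1 they were HCC1143 DMSO replicate 2, SUM159PT DMSO replicate 3 or 24 h replicate 1, HCC38 24 h replicate 2, and HCC70 DMSO or 24 h replicate 3 (up to 0.107). EEPD1 lost its call without HCC1143 24 h replicate 2, HCC38 DMSO replicate 2, HCC70 DMSO replicate 2 or HCC70 24 h replicate 3 (up to 0.0562).

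The fixed lists showed where the 24 h falls lay. Of 39 tested interferon-stimulated genes, 27 fell and 0 rose, and 36 fell when adjusted over the list alone (median −0.54, camera adjusted p = 1.91e-66, and adjusted p = 0.00125 with an estimated correlation). Of 22 JAK-STAT targets, 5 fell, among them OSMR, SOCS3, ICAM1 and BCL3, and 14 fell when adjusted over the list alone (median −0.28, adjusted p = 1.03e-17, and 0.000121 with an estimated correlation). Of 16 JAK-STAT components, OSMR and STAT3 fell, the latter by 0.36 ± 0.08, and 4 fell when adjusted over the list alone (adjusted p = 6.80e-05, and 0.0495 with an estimated correlation). These are the lists whose averaged 24 h call also held with an estimated correlation. Of the NF-kB and inflammatory mediators 1 of 22 fell, CCL2, and 2 when adjusted over the list alone (adjusted p = 6.88e-06, but adjusted p = 0.055 with an estimated correlation). Of the 11 tested antigen presentation genes 1 fell, WARS1, a tryptophanyl-tRNA synthetase, by 0.25 ± 0.06 (a call lost without HCC1143 DMSO or 24 h replicate 2, adjusted p up to 0.0534). When adjusted over the list alone 3 of them fell (adjusted p = 2.28e-05, but adjusted p = 0.164 with an estimated correlation).

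Other lists had few or no called members at 24 h averaged over the lines. The G2/M list (29 genes, 0 called, 0 adjusted over the list alone) had a median of 0.09 and an adjusted p of 2.28e-05, but an adjusted p of 0.357 with an estimated correlation. For the G1/S list (29 genes, 0 called, 0 adjusted over the list alone, median 0.05) these p-values were 0.0184 and 0.564. They were 0.00159 and 0.394 for the immediate early genes (25 genes, 0 and 0, median −0.12). For cholesterol synthesis (21 genes, 0 called, 2 higher when adjusted over the list alone, median 0.08) they were 0.00159 and 0.394. For the amino acid and stress response list (19 genes, WARS1 alone called, 1 adjusted over the list alone, median −0.04) they were 0.0127 and 0.394. Hypoxia and glycolysis (18 genes, 0 called, 1 lower when adjusted over the list alone, median −0.03) gave 0.0178 and 0.341, and the mesenchymal list (15 genes, 0 called, 4 lower when adjusted over the list alone, median −0.07) gave 0.00212 and 0.0519. The medians of these 7 lists are small, and each moved by over 1.5 times when 1 array was left out. The preset-correlation test did not call the basal list (10 genes, adjusted p = 0.356), the luminal list (22 genes, 0.441), the apoptosis regulators (16 genes, 1 higher and 1 lower when adjusted over the list alone, 0.449), the leukocyte markers (12 genes, 0.157) or the endothelial and fibroblast markers (10 genes, 0.843). Each of these 5 had 0 called members and, except for the apoptosis regulators, 0 adjusted over the list alone.

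**Figure D1:**
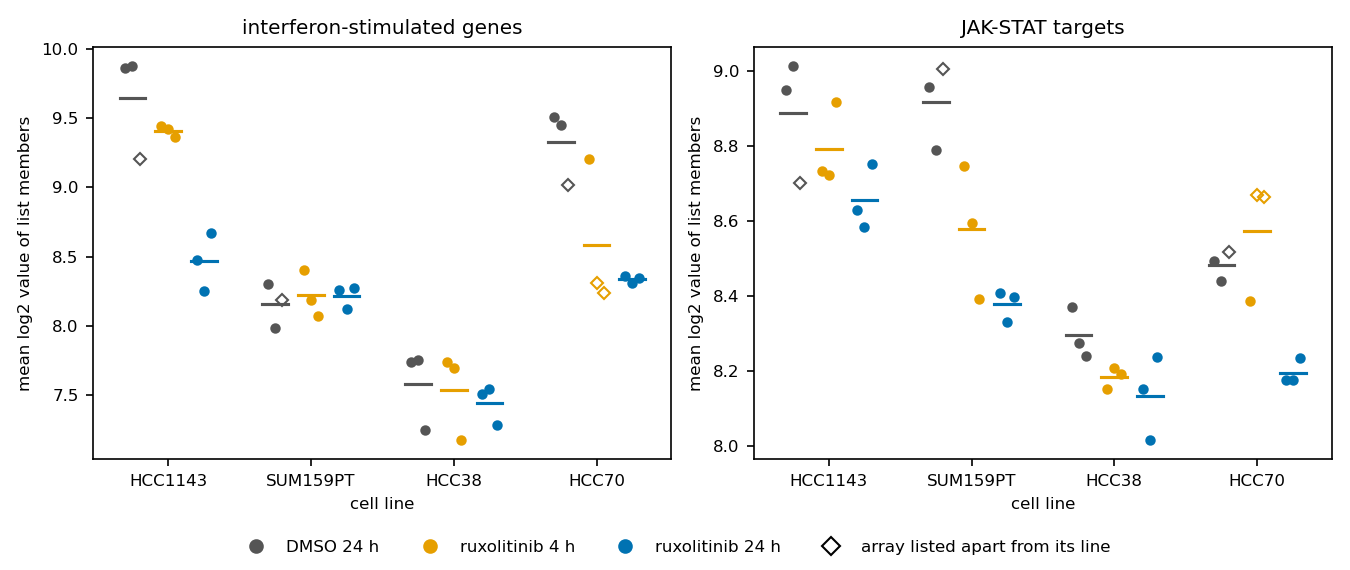
Mean log2 level of the interferon-stimulated list and of the JAK-STAT target list in each of the 36 arrays, by line and treatment. Bars are group means of 3 arrays and open diamonds are the 5 arrays listed apart from the rest of their line; the interferon list went from 9.65 under DMSO to 8.47 at 24 h in HCC1143 and from 9.33 to 8.34 in HCC70.

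In HCC1143, 24 h of ruxolitinib lowered interferon-stimulated genes. IFI44L fell by 4.39 ± 0.57 log2 units (3 arrays against 3, adjusted p = 4.91e-05), to a 24 h mean of 5.82 below the filter level. XAF1 fell as well (−2.41 ± 0.35, adjusted p = 0.000253), and BST2, the antiviral membrane protein tetherin, fell by 1.97 ± 0.31 (adjusted p = 0.0007). IRF7, a transcription factor of the interferon response, fell by 1.16 ± 0.12 and USP18, a negative regulator of interferon signalling, by 1.44 ± 0.21. All 40 called genes were lower, and 26 of them belonged to the interferon-stimulated list, where 33 of 39 fell when adjusted over the list alone (median −1.08, camera adjusted p = 2.10e-79, and adjusted p = 0.000835 with an estimated correlation). Of the 22 JAK-STAT targets 0 were called by limma, with SOCS3 at −0.33 ± 0.18 and OSMR at −0.22 ± 0.13 (median −0.23, adjusted p = 0.00225, but adjusted p = 0.244 with an estimated correlation); 699 genes of this contrast had an unadjusted p under 0.05. The antigen presentation list had a median of −0.26, or −0.45 without DMSO replicate 3 (adjusted p = 1.16e-05, but adjusted p = 0.244 with an estimated correlation). The count of 40 was 17 without DMSO replicate 1, 18 without DMSO replicate 2, 21 without 24 h replicate 1 and 19 without 24 h replicate 2. Without these arrays the calls of DDX60 (−1.73 ± 0.35; adjusted p up to 0.187) and IFIT1 (−1.79 ± 0.41; up to 0.378, also lost without 24 h replicate 3) ended. With the microRNA precursor level as a covariate the count was 17, with the arrays listed apart as a block within lines it was 63, and without all 5 of them 62.

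In HCC70, 24 h of ruxolitinib lowered interferon-stimulated genes and JAK-STAT targets. CCL2 fell by 2.64 ± 0.40 (3 arrays against 3, adjusted p = 0.000378) and CD180, a Toll-like receptor homologue, by 2.23 ± 0.23 (adjusted p = 1.98e-06). IFIT1, an RNA-binding antiviral protein (−2.13 ± 0.41), XAF1 (−1.89 ± 0.35) and DDX60 (−1.70 ± 0.35) fell too. PDCD1LG2, the gene of the immune checkpoint ligand PD-L2, fell by 1.59 ± 0.20 (adjusted p = 3.32e-05) and OSMR by 0.75 ± 0.13. Rises were called for FYB2 (1.39 ± 0.29), the copine gene CPNE8 (1.14 ± 0.23), SCIN, an actin-severing protein (1.04 ± 0.20), ANXA9 (0.98 ± 0.18) and the sulfotransferase gene CHST9 (0.96 ± 0.21). The 24 h mean of PDCD1LG2 (5.85) and the DMSO means of FYB2 (5.91) and CPNE8 (4.94) lay below the filter level. In all 57 genes were called, 11 higher and 46 lower, and 20 of the lower ones were interferon-stimulated genes; 32 of 39 fell when adjusted over the list alone (median −0.91, adjusted p = 1.59e-60, and 0.00425 with an estimated correlation). Of the JAK-STAT targets OSMR alone fell among all genes tested and 2 fell when adjusted over the list alone (median −0.34, or −0.21 without DMSO replicate 3, adjusted p = 2.29e-06, and 0.0241 with an estimated correlation). The G2/M list (median 0.14, adjusted p = 2.30e-06), cholesterol synthesis (0.14, 0.000671) and NF-kB mediators (−0.19, 0.00139) were called with the preset correlation but not with an estimated one (adjusted p = 0.346, 0.386 and 0.263). Without DMSO replicate 3 the median of cholesterol synthesis was 0.015 and that of the NF-kB mediators −0.115, and without DMSO replicate 1 that of cholesterol synthesis was 0.23. Against the DMSO arrays listed with the 24 h arrays alone (3 against 2), the interferon list lay lower by −1.14, CCL2 by −2.69, CD180 by −2.10, IFIT1 by −2.37 and OSMR by −0.88, and ANXA9 higher by 0.78. The count of 57 was 35, 33 and 36 without 24 h replicate 1, 2 or 3 and 7 when the line's own 9 arrays were fitted alone. DDX60 kept its call only without DMSO replicate 3 (adjusted p up to 0.0831). IFIT1 lost it without 24 h replicate 1 (0.0505) and ANXA9 without DMSO replicate 3 (0.0748). SCIN lost it without 24 h replicate 3 or DMSO replicate 3 (up to 0.0959), and FYB2 without 24 h replicate 1 or 2 or DMSO replicate 3 (up to 0.242). CPNE8 lost it without DMSO replicate 2 or 24 h replicate 1 or 3 (up to 0.11), and CHST9 without any 24 h array or DMSO replicate 3 (up to 0.439).

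In SUM159PT, 24 h of ruxolitinib lowered JAK-STAT targets and changed many other genes. ORM2, an acute-phase plasma protein gene, fell by 2.87 ± 0.53 log2 units (3 arrays against 3, adjusted p = 0.0012). IL1RL1, the receptor of interleukin 33, fell as well (−2.65 ± 0.22, 7.70e-09), with LBP, the lipopolysaccharide-binding protein (−2.36 ± 0.36, 0.000196). PRG4, the lubricating proteoglycan (−2.33 ± 0.33), and STEAP4 (−2.28 ± 0.33) fell too. Among the called rises were AQP7P3, an aquaporin pseudogene (2.16 ± 0.31), CCN2, a matricellular growth factor (1.99 ± 0.53), MGP, the matrix Gla protein (1.96 ± 0.45), BMP4, a bone morphogenetic protein (1.83 ± 0.22), and RHAG (1.72 ± 0.20). The 24 h means of ORM2 (4.84) and PRG4 (5.01) and the DMSO mean of AQP7P3 (5.24) lay below the filter level, so these 3 sizes are limits. Probes of ORM2 and AQP7P3 may also bind transcripts of their close paralogues. Of the 22 JAK-STAT targets 10 fell, among them SOCS3 by 1.34 ± 0.18, ICAM1 by 1.17 ± 0.29, OSMR by 0.78 ± 0.13, BCL3 by 0.73 ± 0.15 and LBP. When adjusted over the list alone 11 fell (median −0.49, camera adjusted p = 4.18e-09, and 0.00708 with an estimated correlation). SOCS1, set in advance, stood at 8.64 ± 0.13 (SD) under DMSO, 7.89 ± 0.08 at 4 h and 7.76 ± 0.06 at 24 h in this line. CISH, also set in advance, stood at 7.475 ± 0.40 (SD), 6.91 ± 0.20 and 6.92 ± 0.15. The F tests of differing response called neither (adjusted p = 0.683 and 0.265 for SOCS1 at 4 h and 24 h, 0.850 and 0.295 for CISH). In all 998 genes were called, 625 higher and 373 lower, 406 of them by more than 1.5-fold, and 40 were microRNA precursor genes.

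Among the other lists in SUM159PT at 24 h, the interferon-stimulated genes had a median of 0.06 (adjusted p = 0.6, and 0.948 with an estimated correlation), with 1 called member higher (SAMD9, 0.89) and 1 lower (PLSCR1, −0.81) and 0 adjusted over the list alone. Of the amino acid and stress response list 5 of 19 fell, including the asparagine synthetase gene ASNS by 0.80 and the cystathionine gamma-lyase gene CTH by 1.01 (median −0.27, or −0.14 without DMSO replicate 1, adjusted p = 2.18e-05, but adjusted p = 0.282 with an estimated correlation). Of the NF-kB mediators 1 fell, the serum amyloid gene SAA1 (−1.91, list adjusted p = 0.00175, but 0.282 with an estimated correlation). CDC20 and NEK2, both genes of mitosis, rose by 0.54 and 0.46 in the G2/M list (median 0.17, or 0.34 and 0.07 without DMSO replicate 2 or 3, adjusted p = 0.00573, but 0.737 with an estimated correlation). SAMD9, PLSCR1, ASNS, CTH, SAA1, CDC20 and NEK2 were chosen after their values were seen. The repressors of epithelial genes ZEB1 and SNAI2 were called in different directions, at −0.67 ± 0.19 and 0.90 ± 0.27. The mean log2 level of the microRNA precursor probe sets was 4.94 under DMSO and 4.83 at 24 h in this line, and that of 5 YAP/TEAD target genes was 8.93 and 9.83. The count of 998 was 629 without DMSO replicate 1, 530 without 24 h replicate 2 and 319 without 24 h replicate 3, 350 when the line's own 9 arrays were fitted alone, and 99 with the microRNA precursor level as a covariate. The array listed apart in this line is DMSO replicate 3. With the arrays listed apart as a block within lines 1120 genes were called, and 740 of the 998 kept their call. The calls of ICAM1 (lost without 24 h replicate 2 or 3), CCN2 (without 24 h replicate 2 or 3 or DMSO replicate 3), MGP (without DMSO replicate 2 or 24 h replicate 3), ZEB1 (without any array except DMSO replicate 1 and 24 h replicate 1) and SNAI2 (without any single array) had adjusted p up to 0.0691, 0.0826, 0.0564, 0.11 and 0.13.

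**Figure D2:**
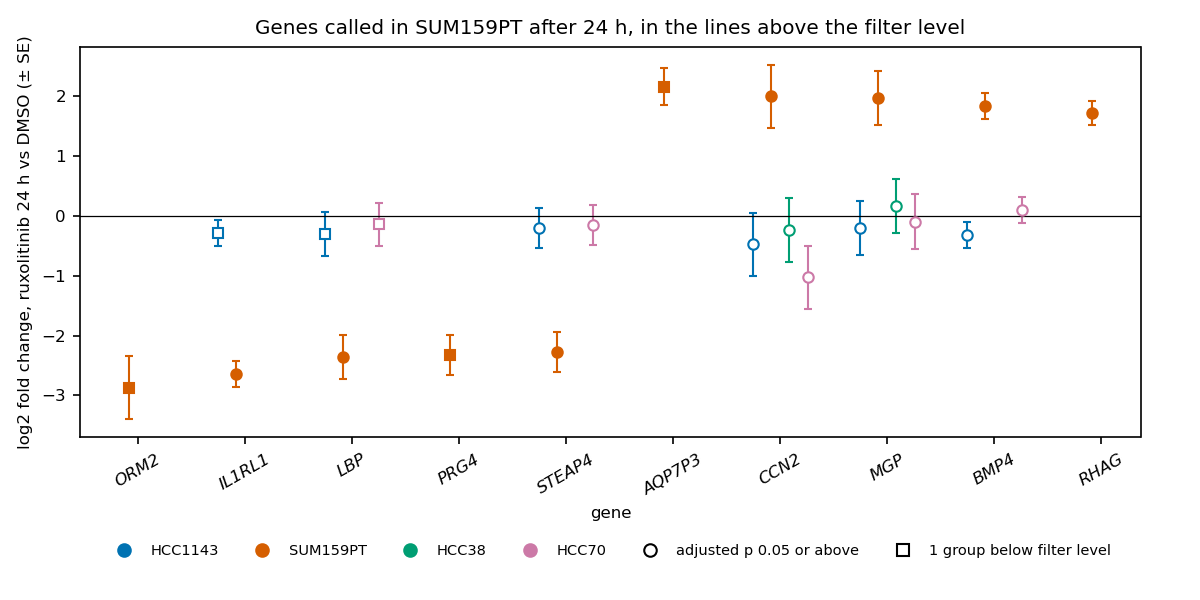
Log2 fold change at 24 h against DMSO in the 4 lines for the 5 called falls and the 5 called rises in SUM159PT with the largest estimates. Points are limma estimates from 3 arrays against 3, bars are their SE, and open points have an adjusted p of 0.05 or more; squares have 1 group below the filter level, and lines with both groups below it are not drawn. CCN2 lay at 1.99 in SUM159PT.

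In HCC38, few genes passed the test at 24 h. OSMR fell by 0.83 ± 0.13 (3 arrays against 3, adjusted p = 0.00545), IFITM3, an interferon-induced membrane protein, fell by 0.98 ± 0.18 (adjusted p = 0.0477, 24 h mean 5.70, below the filter level), and BARX1, a homeobox transcription factor, rose by 0.57 ± 0.10 (adjusted p = 0.0221). SOCS3 lay at −0.76 ± 0.18, STAT3 at −0.56 ± 0.16 and NNMT at −0.98 ± 0.21 without passing (adjusted p = 0.312, 0.659 and 0.145). The 3 calls compare with 567 genes at an unadjusted p under 0.05, where 591 would be expected by chance. Of 22 JAK-STAT targets OSMR alone was called, and 1 rose and 4 fell when adjusted over the list alone; the median of the list was −0.02 (between −0.11 and 0.03 without 1 array), its mean −0.16, and its adjusted p 0.00736, but the adjusted p was 0.408 with an estimated correlation. The interferon-stimulated list (1 called, median −0.13, and −0.0389, −0.0229, −0.315 and −0.0442 without DMSO replicate 1, 2 or 3 or 24 h replicate 3) had the same adjusted p of 0.00736, and 0.853 with an estimated correlation, and the JAK-STAT components 0.0303 and 0.408. With the replicate numbers as pairs the call of IFITM3 ended (adjusted p = 0.0825). The G1/S list (camera adjusted p = 0.0327, upward) and the mesenchymal list (0.0499, downward) then passed at the preset correlation. An estimated correlation was not tried with the pairs. The count of 3 was 0 without DMSO replicate 2, 1 without 24 h replicate 3, 0 with the line's own 9 arrays fitted alone and 1 without the 5 arrays listed apart, none of which is from HCC38. IFITM3 kept its call only without 24 h replicate 2 (adjusted p up to 0.506). BARX1 lost it without DMSO replicate 2 or 24 h replicate 1 or 3 (up to 0.315) and OSMR without DMSO replicate 2 (0.0762).

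The 24 h response differed between the lines for 224 genes by the moderated F test. CD180 rose by 1.04 ± 0.23 in SUM159PT and fell by 2.23 ± 0.23 in HCC70 (adjusted p of the difference 7.28e-06). IL1RL1 fell in SUM159PT (7.28e-06) and lay below the filter level in both groups in HCC38 and HCC70 and at 24 h in HCC1143. IRF7 fell by 1.16 in HCC1143 and by 0.69 in HCC70 and lay at 0.22 in SUM159PT and 0.08 in HCC38 (5.05e-05), and TRIM14, TRIM21, USP18, SP110 and XAF1, all induced by interferon, differed likewise (adjusted p from 0.000425 for TRIM14 to 0.007 for XAF1). The cytoskeletal gene NEXN was at 1.58 ± 0.25 in SUM159PT and −1.02 ± 0.25 in HCC70, there to a 24 h mean of 5.77 below the filter level. TMC5, a transmembrane channel-like gene, fell by 1.40 ± 0.16 in HCC70 and was higher by 0.03 in HCC1143 without a call (both genes 0.00106), and lay below that level in both groups in HCC38 and at 24 h in SUM159PT. For SOCS3, OSMR and STAT3 the 24 h response did not differ between lines past the threshold (adjusted p = 0.0783, 0.131 and 0.419). HCC1143 and HCC70 shared 24 called falls where 0.156 would be shared by chance (one-sided Fisher exact p = 5.60e-51, adjusted over 9 overlaps 5.04e-50; genes are not independent), and HCC1143 and SUM159PT shared 0 of their 40 and 373, with 1.26 expected (p = 1). OSMR was among the called falls of SUM159PT, HCC38 and HCC70.

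Whole lists also differed between lines at 24 h. The interferon-stimulated list changed more in HCC1143 than in HCC38 (median difference −1.002, adjusted p = 0.0434 with an estimated correlation) and more in HCC70 than in HCC38 (0.87 for HCC38 minus HCC70, adjusted p = 0.0442). The median differences HCC1143 minus SUM159PT (−1.15) and SUM159PT minus HCC70 (1.06) had adjusted p = 5.66e-19 and 1.78e-18 at the preset correlation, but adjusted p = 0.0661 for both with an estimated correlation. The JAK-STAT targets fell more in SUM159PT than in HCC38 (median difference −0.28, adjusted p = 0.0434 with an estimated correlation). The count of 224 genes was 149 without HCC1143 DMSO replicate 2, 350 without HCC1143 24 h replicate 3, 105 without SUM159PT 24 h replicate 2, 79 without SUM159PT 24 h replicate 3, and 8 with the microRNA precursor level as a covariate.

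**Figure D3:**
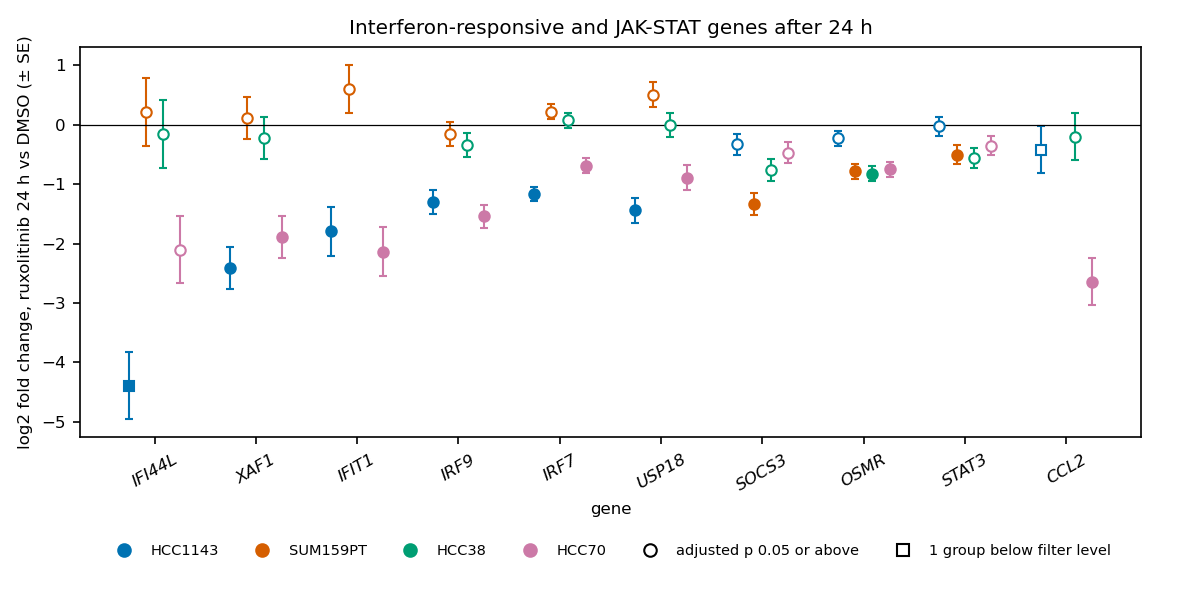
Log2 fold change at 24 h against DMSO in the 4 lines for interferon-response genes (IFI44L, XAF1, IFIT1, IRF9, IRF7, USP18) and cytokine-signalling genes (SOCS3, OSMR, STAT3, CCL2). Points are limma estimates from 3 arrays against 3, bars are their SE, and open points have an adjusted p of 0.05 or more; squares have 1 group below the filter level, and lines with both groups below it are not drawn. IRF9 lay at −1.30 in HCC1143, −1.54 in HCC70, −0.15 in SUM159PT and −0.34 in HCC38.

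Averaged over the lines, 3 genes were lower after 4 h of ruxolitinib than after 24 h of DMSO. The 4 h contrasts differ in time as well as in drug, and the arrays cannot tell these apart. SOCS3 fell by 0.71 ± 0.09 log2 units (12 arrays against 12, adjusted p = 0.000146), IFIT5, an RNA-binding interferon-induced gene, by 0.46 ± 0.07 (0.00248) and RBBP6, an RB-binding protein gene, by 0.26 ± 0.05 (0.0306). No gene rose among the 11814, and 499 had an unadjusted p under 0.05. Of 22 JAK-STAT targets SOCS3 alone was called, and 3 fell when adjusted over the list alone (median −0.11, or −0.07 without SUM159PT 4 h replicate 3, camera adjusted p = 1.63e-07, and 0.0252 with an estimated correlation; adjusted p = 0.0685 by fry). Of 39 interferon-stimulated genes IFIT5 alone was called, and 7 fell when adjusted over the list alone (median −0.21, adjusted p = 2.36e-25, but 0.0939 with an estimated correlation and 0.191 by fry). All 29 G1/S genes had positive values, 0 of them called (median 0.09, or 0.04 without SUM159PT DMSO replicate 3, adjusted p = 1.59e-07, but 0.691 with an estimated correlation). The count of 3 was 13 without HCC70 4 h replicate 1, 6 without HCC38 DMSO replicate 3, and 7 with the arrays listed apart as a covariate. RBBP6 kept its call only when the array left out was SUM159PT DMSO replicate 3 or 4 h replicate 2, HCC38 DMSO replicate 3 or 4 h replicate 3, or HCC70 DMSO replicate 3 or 4 h replicate 1 (adjusted p up to 0.108).

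At 4 h SUM159PT and HCC70 showed list-wide changes. In SUM159PT SOCS3 fell by 1.63 ± 0.18 (3 arrays against 3, adjusted p = 8.68e-06), BCL3, a coactivator of NF-kB, by 0.96 ± 0.15 (0.0021). The protease gene KLK6 fell by 1.70 ± 0.33, the AP-1 gene JUNB by 1.07 ± 0.21, the kinase gene MAP3K8 by 1.07 ± 0.21 and DEPP1 by 1.01 ± 0.18. In turn ACOT4 (0.82 ± 0.16) and RTN1 (0.80 ± 0.16) rose. MTTP, a lipid transfer protein, was called higher with both means (5.09 and 5.74) below the filter level. Of its JAK-STAT targets 3 fell, and 5 when adjusted over the list alone (median −0.29, or −0.13 without 4 h replicate 3, adjusted p = 1.32e-09, and 0.00698 with an estimated correlation). The list changed differently in HCC70, where its mean was 0.09 ± 0.09 (median difference −0.16, adjusted p = 0.0225 with an estimated correlation). Among the earlier HCC70 arrays (1 against 2) the list mean differed by −0.08, and among those listed apart (2 against 1) by 0.15. The positive mean in HCC70 thus rests on the arrays listed apart, and a difference between array sets stays open. The G1/S and G2/M lists of SUM159PT had medians of 0.30 and 0.26 with 0 called members by limma. When adjusted over the list alone 14 G2/M genes were higher. The camera adjusted p of the 2 lists was 1.12e-11 and 7.49e-13, but 0.277 and 0.26 with an estimated correlation. Without DMSO replicate 3, listed apart, these medians were 0.09 and 0.12, and without DMSO replicate 2 that of G1/S was 0.46. In all 10 genes were called, 3 higher and 7 lower, against 945 at an unadjusted p under 0.05. Leaving out 1 array gave 6 (DMSO replicate 1), 58 (DMSO replicate 2), 4 (DMSO replicate 3), 5 (4 h replicate 1), 4 (4 h replicate 2) or 1 (4 h replicate 3), and of the named calls that of SOCS3 held without any 1 array. The count was 2 with the line's own arrays alone, 4 with the array listed apart as a block and 5 without the arrays listed apart.

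In HCC70 at 4 h, IFIT1 fell by 2.18 ± 0.41, SP110 by 1.02 ± 0.20 and IFIT5 by 0.78 ± 0.14, and MT1M, a metallothionein gene, rose by 3.16 ± 0.60 from a DMSO mean of 5.60, below the filter level (each adjusted p = 0.042, 3 arrays against 3). Of its 39 interferon-stimulated genes these 3 fell, and 28 when adjusted over the list alone (median −0.70, adjusted p = 5.30e-45, and 0.0195 with an estimated correlation). The immediate early genes (median 0.35, 0 called by limma, adjusted p = 1.88e-10) and the NF-kB mediators (median 0.11, 0 called by limma, 2 higher when adjusted over the list alone, adjusted p = 0.013) were called upward with the preset correlation and not with an estimated one (adjusted p = 0.263 and 0.53). The median of the immediate early genes was 0.62 without 4 h replicate 1 and 0.23 without DMSO replicate 2. That of the NF-kB mediators lay between 0.02 (without 4 h replicate 3) and 0.225 (without DMSO replicate 3). In all 609 genes had an unadjusted p under 0.05. Of the 3 arrays at 4 h, 2 are listed apart from the rest, with 1 of the 3 DMSO arrays. Among the earlier arrays (1 against 2) the interferon list differed by −0.28, IFIT1 by −0.85, SP110 by −0.58, MT1M by 0.53 and the immediate early genes by 0.05, and among the arrays listed apart (2 against 1) by −0.75, −2.50, −1.01, 4.57 and 0.37. The NF-kB mediators differed by −0.01 and 0.30 in these comparisons. The count of 4 was 257 without 4 h replicate 1, 8 without DMSO replicate 3, and 0 without DMSO replicate 1, DMSO replicate 2, 4 h replicate 2 or 4 h replicate 3. It was also 0 without the filter, with the line's own arrays alone and without the arrays listed apart, and 1 with a variance trend.

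In the remaining lines single genes passed at 4 h. In HCC1143 TRIM21, an interferon-induced ubiquitin ligase, fell by 0.84 ± 0.16 and IFIT5 by 0.78 ± 0.14, and the pseudogene ADAM20P1 rose by 1.04 ± 0.20 (adjusted p = 0.0457, 0.0457 and 0.0482), against 518 genes at an unadjusted p under 0.05. These calls were lost without any 1 of the arrays, except that TRIM21 and IFIT5 kept theirs without DMSO replicate 3 (adjusted p up to 0.528 and 0.443; ADAM20P1 up to 0.958). Its interferon-stimulated list had 1 called member and a median of −0.16 (adjusted p = 1.17e-05, but 0.963 with an estimated correlation). The median was −0.43 without DMSO replicate 3, listed apart, −0.08 without DMSO replicate 2 and −0.12 without DMSO replicate 1. Its count of 3 was 0 without DMSO replicate 1, DMSO replicate 2 or any 1 of the 4 h arrays, 0 without the filter, 0 with the line's own arrays alone and 0 with the microRNA precursor covariate. In HCC38 BARX1 rose by 0.61 ± 0.10 (adjusted p = 0.0126), against 415 genes at an unadjusted p under 0.05. With the replicate numbers as pairs 2 genes were called there, and 0 were called without DMSO replicate 2, with the line's own arrays alone or without the arrays listed apart. BARX1 lost its call without DMSO replicate 2 or 4 h replicate 2 or 3 (adjusted p up to 0.148). No gene differed in its 4 h response between the lines by limma's F test, and 706 had an unadjusted p under 0.05 where 591 would be expected by chance. That count of 0 was 78 without HCC70 4 h replicate 1.

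Between 4 h and 24 h of drug, averaged over the lines, OSMR fell by 0.46 ± 0.06 log2 units (12 arrays against 12, adjusted p = 0.000934), ICAM1 by 0.79 ± 0.14, IL1RL1 by 0.58 ± 0.11, PDCD1LG2 by 0.48 ± 0.10 and IFITM3 by 0.46 ± 0.09. Over the same arrays ANXA9 (0.46 ± 0.09), REPS2 (0.44 ± 0.09), NPNT (0.41 ± 0.09), TMEM254-AS1 (0.35 ± 0.07) and GLP2R (0.34 ± 0.07) rose, with the 4 h mean of TMEM254-AS1 (5.60) below the filter level. SOCS3 lay at −0.01 ± 0.09 and IFIT5 at −0.01 ± 0.07 in this comparison. Of the interferon-stimulated genes 3 fell (IFITM3, IRF7 and TRIM14), and 25 when adjusted over the list alone (median −0.32, adjusted p = 6.27e-25, but 0.0788 with an estimated correlation). The JAK-STAT targets (2 called, median −0.16, adjusted p = 4.43e-06), the NF-kB mediators (median −0.20, 4.43e-06) and the immediate early genes (median −0.22, 3.19e-05) passed with the preset correlation and not with an estimated one (adjusted p = 0.0664, 0.0788 and 0.359). The median of the immediate early genes was −0.14 without HCC38 4 h replicate 3 and −0.15 without HCC70 4 h replicate 2. In all 16 genes were called, 8 higher and 8 lower. The call of OSMR held without any 1 of the 24 arrays, and each other call named here was lost without at least 11 of them in turn (adjusted p up to 0.113) and kept without HCC70 4 h replicate 1 and without SUM159PT 4 h replicate 3. Of the 3 HCC70 arrays at 4 h, 2 are listed apart, and no 24 h drug array is. With a block for the arrays listed apart within lines 39 genes were called, and 10 of the 16 kept their call. The count of 16 was 103 without HCC70 4 h replicate 1 and 46 without SUM159PT 4 h replicate 3. It was 1 without HCC1143 4 h replicate 3, SUM159PT 4 h replicate 1 or 2, SUM159PT 24 h replicate 3, HCC70 4 h replicate 2 or 3, or HCC70 24 h replicate 1 or 2. It was 2 without HCC1143 24 h replicate 1, HCC38 4 h replicate 2 or 3, or HCC38 24 h replicate 1. It was 3 without HCC1143 4 h replicate 1 or 2 or HCC70 24 h replicate 3, and 4 without SUM159PT 24 h replicate 1. It was 5 without HCC38 4 h replicate 1 or 24 h replicate 2, 6 without SUM159PT 24 h replicate 2, and 7 and 9 without HCC1143 24 h replicates 3 and 2.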

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

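The tests of the microRNA precursor covariate, of the detection floor and of the arrays listed apart were chosen after the results they bear on were seen; the 2 tests of how many SUM159PT calls follow the microRNA or the YAP/TEAD level, and the splits of the arrays, were set before their values were computed. The criterion of the floor test was also revised after its values were seen, to compare the same genes between lines; the earlier criterion, set on each line alone, had left HCC38 open and had the same outcome for SUM159PT. The microRNA and YAP/TEAD covariates, the block, its fits without 1 array and the fit without the arrays listed apart were added after seeing the data.

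SUM159PT stood out with 998 called genes at 24 h, against 3 to 57 in the other lines, and with 1648 called probe sets that carry no gene name (536 higher, 1112 lower). The tables argue against an array-wide shift as the whole cause of the fall of the JAK-STAT targets: with the microRNA precursor level as a covariate the list mean was −0.71 ± 0.10, and −0.54 ± 0.09 without it (−0.62 ± 0.09 with the YAP/TEAD level as a covariate). For the calls as a whole such a shift stays open, since 73.1% of 958 called genes followed the microRNA level in the other 3 lines in the direction needed, against 61.5% of uncalled genes, and 4 of 100 shuffles within groups gave as much; with the covariate 94 of the 998 genes were still called and 997 kept their sign, while the median size went from 0.53 to 0.41 and the median SE from 0.14 to 0.17, so the calls ended by both a smaller size and a wider error. A difference in culture density also stays open: the YAP/TEAD level rose by 0.90, but 57.9% of 956 called genes followed that level elsewhere against 52.8% of uncalled ones, and 25 of 100 shuffles gave as much. The shift, density and a response particular to this line cannot be told apart for the calls as a whole, because treatment and these levels move together in 6 arrays; the real split gave 998 calls and the highest other split 27, but 10 splits are too few for a share under 0.05.

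Interferon-stimulated genes fell at 24 h in HCC1143 and HCC70, not in SUM159PT (list adjusted p = 0.6; list mean 0.06 ± 0.21, or 0.45 ± 0.16 with the YAP/TEAD level, which itself rose there, as a covariate), with a slight fall in HCC38 (median −0.13, adjusted p = 0.00736, but 0.853 with an estimated correlation). Among pairs of lines the difference held in camera with an estimated correlation for HCC1143 minus HCC38 (median −1.002, adjusted p = 0.0434) and HCC38 minus HCC70 (median 0.87, adjusted p = 0.0442). For HCC1143 minus SUM159PT (median −1.15) and SUM159PT minus HCC70 (median 1.06) it did not hold (adjusted p = 0.0661 for both). A floor of detection is argued against as the whole cause in SUM159PT, where the 23 members at least 2 log2 units above the filter level under DMSO changed by 0.0468 ± 0.232, higher than the same genes in HCC1143 by 1.38 ± 0.33 and in HCC70 by 1.10 ± 0.33. It is likewise argued against in HCC38, where the 15 such members changed by −0.136 ± 0.201, higher than in HCC1143 by 1.07 ± 0.28 and in HCC70 by 0.88 ± 0.28, which leaves a smaller fall in that line open. The microRNA-tracked shift is argued against for HCC1143, where the list mean was −1.18 ± 0.26 with the covariate and −1.18 ± 0.21 without, so a difference in ongoing interferon signalling between the lines remains a hypothesis, untested by any measure of interferon itself.

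In HCC70 at 4 h the immediate early genes had positive values and the interferon list fell, and 2 of the 3 treated arrays and 1 of the 3 DMSO arrays are listed apart. With a block for those arrays the immediate early mean was 0.21 ± 0.14 (0.44 ± 0.18 without, 0.16 ± 0.10 with the YAP/TEAD covariate) and the interferon mean −0.51 ± 0.16 (−0.74 ± 0.21 without, −0.46 ± 0.15 with that covariate), and the interferon list kept its call with the block at the preset correlation. Within the earlier arrays the immediate early difference was 0.05 and within the arrays listed apart 0.37 (1 array against 2, and 2 against 1), where the interferon differences were −0.275 and −0.748, and the criterion for this test was revised after its value was seen. The rise cannot be told apart from a difference between the array sets, because each set holds a single array of 1 group, while the fall, below 0 by over 3 SE with the block, counts against such a difference as its whole cause but leaves it open, since without DMSO replicate 3 the mean with the block was −0.275 ± 0.215. The split that parts the arrays listed apart from the earlier ones called 1303 genes against 4 for the real one, and 2 of the 10 splits gave at least 4, too few splits for a share under 0.05.

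Single genes differed between lines in their 24 h response, 224 in all by the moderated F test, and the genes selected for naming had these adjusted p-values: CD180 7.28e-06, IL1RL1 7.28e-06, IRF7 5.05e-05, TRIM14 0.000425, TRIM21 0.00106, BMP4, NEXN and TMC5 0.00106, RHAG 0.00112, USP18 0.00126, SP110 0.00177, GLP2R 0.00181, EPHB6 0.00292, IFIT5 0.00314, IFI44L 0.00349, BST2 and XAF1 0.00700, AQP7P3 0.00719, IRF9 0.00741, ADAM20P1 and IFIT1 0.0102, TFCP2L1 0.0102, PRG4 0.0134, PDCD1LG2 0.0149, MTTP 0.0164, BARX1 0.0172, CCL2 0.0172, LBP 0.0183, CPNE8 0.0214, STEAP4 0.0227, DEPP1 0.0257, CRIP2 and EPCAM 0.0275, REPS2 0.0286, CIDEC 0.0300, SCIN 0.0424 and DDX60 0.0497. The log2 fold changes behind them ran from −4.39 for IFI44L in HCC1143 to 2.16 for AQP7P3 in SUM159PT, each from 3 arrays against 3 and with 1 group below the filter level, and EPCAM lay below it in both groups in SUM159PT (5.46 and 4.26). The count of 224 was 79 without SUM159PT 24 h replicate 3, 105 without SUM159PT 24 h replicate 2, 149 without HCC1143 DMSO replicate 2 and 350 without HCC1143 24 h replicate 3. The JAK-STAT target list also differed between SUM159PT and HCC70 at 4 h (median difference −0.16, adjusted p = 0.0225) and between SUM159PT and HCC38 at 24 h (−0.28, adjusted p = 0.0434), both with an estimated correlation. In HCC70 at 4 h the list mean differed from DMSO by −0.08 among the earlier arrays and by 0.15 among those listed apart, so a difference between array sets stays open there.

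Probe sets without a gene name, outside the comparisons of genes, also passed the test in treated against DMSO arrays. Of 18879 tested, 37 were called in HCC1143 at 24 h (5 higher, 32 lower), 35 in HCC70 at 24 h (3 higher, 32 lower), 57 in the averaged 24 h contrast (10 higher, 47 lower), 3 in SUM159PT at 4 h, 3 in HCC70 at 4 h and 9 between 24 h and 4 h of drug (1 higher, 8 lower).

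Other splits of the same arrays were tried for each count. The share of splits with at least as many calls was under 0.05 for the averaged 24 h contrast (105 genes, highest other split 4). Only the real split of 100 was as large. It was also under 0.05 for 24 h against 4 h of drug (16, highest other 5, 1 of 100). The same held for the DMSO groups (9349, highest other 7501, 1 of 100). For the differing 24 h response (224) 2 of 100 splits were as large, and another split called 300. For the averaged 4 h contrast (3, highest other 549) 22 of 100 were as large. The splits, within lines or of the 12 vehicle arrays, were drawn without regard to the HCC38 numbers or the arrays listed apart. For the treatment contrasts these shares therefore cannot separate treatment or chance from such structure, and no 24 h drug array is listed apart. For the differing 4 h response the real count was 0 (highest other 1305), so all 100 splits gave at least as many by construction and the count tests nothing. Within lines 10 splits are too few for a share under 0.05, and the real and highest other values at 24 h were 40 and 17 in HCC1143 (1 split as large), 57 and 1 in HCC70 (1) and 3 and 12 in HCC38 (3). At 4 h they were 3 and 9 in HCC1143 (2), 10 and 116 in SUM159PT (2) and 1 and 142 in HCC38 (5). Splits that call several times the real count, 549, 116 and 142 among them, point to a structure of the arrays other than treatment. In HCC38, whose numbers were read as pairs, the other splits that part all 3 pairs called 0, 1 and 0 genes at 4 h against 1. At 24 h they called 0, 0 and 1 against 3. The splits with more calls keep pairs together.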

How the results depend on the processing

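The microRNA precursor covariate, the block for arrays listed apart within lines and the fit without those 5 arrays were chosen after seeing the data; the other alternatives were planned. Apart from leaving out arrays, named-gene values kept direction and side of the threshold in 1546 cases, lost the call in 221, gained it in 10 and reversed in 0. List tests stayed on their side in 1305 cases, lost the call in 137, gained it in 42 and reversed in 12. With 1 array left out, named-gene values kept their side in 1835 cases, lost the call in 521, gained it in 8 and reversed in 0, and list tests kept their side in 1777, lost the call in 28 and gained it in 31. Counts stayed within 1.5 times in 115 cases with 1 array left out and 108 otherwise, moved further in 59 and 38, and rose from 0 in 6 and 3. Unless the construction shows it (fewer arrays, more genes tested), the cause was not tested. Signal over background limits dim genes: a gene needed 1 group mean above 5.92, so folds with a group below that level are limits. Where an array left out leaves 2 in a group, the spread is shared by all groups.

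Without the filter 0 genes were called in HCC1143 at 4 h, 0 in HCC70 at 4 h and 1 between 24 h and 4 h of drug. With each line's own arrays alone the counts were 0 (HCC1143), 2 (SUM159PT), 0 (HCC38) and 0 (HCC70) at 4 h, and 350 (SUM159PT), 0 (HCC38) and 7 (HCC70) at 24 h. A variance trend with robust moderation gave 1 in HCC70 at 4 h and 8 between 24 h and 4 h. The covariate for arrays listed apart gave 7 in the averaged 4 h contrast and 30 between 24 h and 4 h. The microRNA covariate gave 0 in HCC1143 and 2 in HCC38 at 4 h, 17 in HCC1143 and 99 in SUM159PT at 24 h, 5 between 24 h and 4 h and 8 for the differing 24 h response. The block for arrays listed apart within lines gave 4 in SUM159PT at 4 h, 63 in HCC1143 at 24 h, 39 between 24 h and 4 h and 2 for the differing 4 h response. Of the 16 calls between 24 h and 4 h, 10 were among those 39. Without the 5 arrays listed apart these were 5, 62, 26 and 2, with 0 in HCC38 and HCC70 at 4 h and 1 in HCC38 at 24 h.

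With the replicate block the counts were 2 (HCC38) and 17 (HCC70) at 4 h, 67 (HCC1143), 1835 (SUM159PT) and 107 (HCC70) at 24 h, 5 and 244 in the averaged contrasts at 4 h and 24 h, 178 between 24 h and 4 h, and 1 and 803 for the differing response at 4 h and 24 h. Same-numbered arrays correlated over 0.1 in 5 of 9 pairs in HCC1143, 4 of 9 in SUM159PT and 7 of 9 in HCC70, and 4, 4 and 5 of the 9 arrays of these lines matched their own number best, a hint from the data only, so no pairing was read from their numbers. In HCC38 the numbers were read as pairs, with 7 of 9 arrays best with their own. There the block changed no call other than the 4 h count, IFITM3 and the G1/S and mesenchymal lists given with its results.

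For lists, fry gave an adjusted p of 0.0685 for the JAK-STAT targets and 0.191 for the interferon genes averaged at 4 h, and an estimated correlation 0.0939 for the latter. Directions reversed as follows, with the adjusted p after reversal. The G2/M list in HCC1143 at 4 h turned upward with the block for arrays listed apart (0.017) and without those arrays (0.0167), and the G1/S list in SUM159PT at 24 h turned downward (0.0398 and 0.0419), as did cholesterol synthesis between 24 h and 4 h (0.908 and 0.749). Without those arrays the NF-kB list in HCC70 at 4 h turned downward (0.532), the G2/M list there upward (0.372), and the NF-kB and immediate early lists averaged at 4 h downward (0.0284 and 0.0456). With the microRNA covariate the immediate early list in HCC1143 at 24 h turned upward (0.524) and its G2/M list downward (0.0311).

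Leaving out each array in turn gave 0 to 2 genes in HCC1143, 1 to 58 in SUM159PT, 0 to 1 in HCC38 and 0 to 257 in HCC70 at 4 h, 17 to 60, 319 to 921, 0 to 4 and 33 to 48 at 24 h, 2 to 13 and 71 to 125 in the averaged contrasts, 1 to 103 between 24 h and 4 h, 0 to 78 and 79 to 350 for the differing response at 4 h and 24 h, and 9127 to 9378 between DMSO groups.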

Other observations

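The test of a relation between the interferon and YAP/TEAD levels was chosen after the levels were seen, and its criterion was revised after the value was seen, as was the way HCC38 arrays were permuted: with those arrays permuted singly the relation in HCC38 had passed.

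Levels of markers of other cell types under DMSO are given by line, and differences between lines were not tested for these lists. Of the 10 tested endothelial and fibroblast members, 7 in HCC1143, 8 in SUM159PT, 6 in HCC38 and 6 in HCC70 lay above the filter level under DMSO. Being tested required passing that level in at least 1 group, so these shares are raised by the filter. The other members of the list had no named probe set or lay at or below the level in every group. The mean levels that follow also cover tested members only. The endothelial and fibroblast list had mean log2 levels under DMSO of 6.96 ± 0.06 (SD, n = 3) in HCC1143, 7.33 ± 0.08 in SUM159PT, 6.65 ± 0.15 in HCC38 and 6.73 ± 0.02 in HCC70, and the leukocyte list of 7.24 ± 0.08, 8.11 ± 0.15, 7.08 ± 0.08 and 6.96 ± 0.11. In SUM159PT at 24 h, 3 endothelial genes were called higher, PECAM1, an adhesion molecule (0.93), KDR, a receptor of vascular endothelial growth factor (1.02), and TIE1 (0.38, from a DMSO mean of 5.66 below the filter level), chosen after their values were seen. IL6R, the receptor of interleukin 6, rose by 1.03 in that line at 24 h, while IFNGR1, a subunit of the interferon gamma receptor, fell by 0.33 and IL4R, a subunit of the interleukin 4 receptor, by 0.55 ± 0.13; IL6R and IFNGR1 were also chosen after their values were seen. The glycolytic gene HK2 fell by 1.08 there, and the pro-apoptotic genes BCL2L11 and APAF1 went apart, at −0.65 and 0.76, again chosen after their values were seen.

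A hypothesis from these data was that cultures with a higher level of YAP/TEAD targets hold a lower level of interferon-stimulated genes, and the arrays leave it open. Within groups, over the 30 arrays left without those listed apart and without HCC70 4 h replicate 1, which their omission leaves alone in its group, Pearson's r was −0.451 (permutation p = 0.301, adjusted over 6 relations 0.452) and Spearman's rho −0.333 (permutation p = 0.427, adjusted 0.64). The permutations kept arrays of the same number together in HCC38, where the numbers were read as pairs. In HCC38 alone r was −0.884 and rho −0.733 over 9 arrays. These were read as 3 experiments, and the permutation p of 0.167 is the smallest that 6 permutations can give. Replicate 3 had the highest YAP/TEAD level and the lowest interferon level in all 3 groups of that line, and without it r was 0.00558 in HCC38 and −0.109 over the remaining 27 arrays (permutation p = 0.76). In HCC1143 r was −0.333 (exact permutation p = 0.63) and in SUM159PT −0.0647 (exact permutation p = 0.907), each over 9 arrays. The HCC70 arrays fall into 2 clusters by the YAP/TEAD level, 8.10 to 8.32 in the earlier arrays and 9.73 to 9.95 in those listed apart, so r in that line (−0.955, permutation p = 0.0972, adjusted 0.292) and over all 36 arrays (−0.755, permutation p = 0.0111, adjusted 0.0666) follows the difference between these clusters and is not read as a relation between cultures.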
